A study of Mus musculus with 54 samples.

How the data were processed

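Small RNA was sequenced from liver, epididymal white adipose tissue (eWAT) and sperm of male C57BL/6 mice of the F0 generation. Per the labels, mice entered the diets at 6 weeks of age and were sampled at 24 weeks. LF mice ate a low-fat diet for 18 weeks, HF mice a high-fat diet for 18 weeks, and HFLF mice a high-fat diet for 9 weeks and then a low-fat diet for 9 weeks. The diet protocol prints 1 diet as "HLD", which was read as the high-fat diet named elsewhere in the labels. Each tissue had 6 libraries per diet, 54 in all. The labels number the mice within a diet and do not otherwise state that replicates are separate animals, so p-values measure the spread between these samples.

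Libraries were made by the authors with the NEXTFLEX Small RNA-seq Kit v3 and sequenced on a NovaSeq 6000. The labels name cutadapt, Bowtie and the genome build GRCm38.p6, without versions; the miRNA reference and the counting program are not stated. The deposited liver and eWAT tables hold raw counts per mature miRNA, 1966 names each, the same in both, including names at 0 in every library. The eWAT table repeats the 18 liver columns exactly, and these were taken from the liver table alone. The deposited sperm table holds values on a log2 scale for 79 miRNAs that the authors chose, with a further column that gives a cluster number from 1 to 3 (other: no measurement). The transformation and the rule of choice are not stated. All 18 F0 sperm columns share a lowest value of 1.72, at which 27 to 37 of the 79 values of a library lie, and the highest value is 18.6. A further 18 sperm columns of the F1 generation match no sample of this series and were not used. Columns coded C, H and R in liver and eWAT, and CD, HF and RE in sperm, were read as LF, HF and HFLF; the sources do not define C and R, so the assignment of these groups rests on that reading.

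Liver and eWAT counts were each fitted with edgeR 4.0.16 in R 4.3.3. The fit used filterByExpr with the diet as group, TMM (trimmed mean of M-values) scaling and the quasi-likelihood test, with all 3 diets in 1 fit per tissue. This left 422 miRNAs in liver and 571 in eWAT. Sperm values were fitted as deposited with limma 3.58.1 (eBayes with trend), since no counts are given, and fold changes of sperm values hold only if the scale is log2. Each tissue had the contrasts HF against LF, HFLF against LF and HFLF against HF. A call is a Benjamini-Hochberg adjusted p below 0.05 over all miRNAs of a tissue and contrast, 2-sided. SE is the standard error of the log2 fold change. CPM are counts scaled to 1000000 per TMM-scaled library, and log2 CPM used a prior count of 2. The number of libraries that show a direction is the number of the first group's 6 libraries that lie beyond the mean of the second group, both on the log2 scale. With 6 against 6 libraries, 0.216% of the 924 possible splits separate a miRNA without overlap by chance in either direction.

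The 10 mature let-7 names (miR-98 included) were summed per library as log2 of their summed CPM and compared with a 2-sided exact permutation test, with adjustment over the 3 contrasts of a tissue. In sperm only let-7a-5p is listed. The smallest p that this design allows is 0.00216. The 19 miRNA lists were tested with fry, which asks whether the members of a list move on balance in a single direction; lists with fewer than 3 measured members were not tested. Camera with an estimated correlation between members served as the alternative, and its p is given below as that with an estimated correlation. It asks another question than fry: whether the members of a list move more than the other miRNAs. No list passed camera in any tissue or contrast, so none was shown to move more than the other miRNAs. The lists cover let-7, lipid and fatty liver, miR-29, miR-30, miR-183/96/182, miR-17-92 and paralogs, the Dlk1-Dio3 imprinted cluster, and sperm miRNAs of paternal stress and diet studies. They also cover markers of hepatocytes, adipocytes, brown and beige fat, leukocytes and macrophages, erythroid cells, endothelium, fibroblasts and stellate cells, striated muscle, epithelium (miR-200), male germ cells and the X-linked testis cluster. The difference between the diet effects of liver and eWAT was tested as the interaction of tissue and diet in 1 edgeR fit of both tables.

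Designs, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule names the 5 most abundant miRNAs of a tissue. For HF against LF it names the 10 higher and 10 lower miRNAs with the largest change among those called, and for the other contrasts 5 each way. Where none passes it names the 3 of smallest p. It adds every measured let-7 member and up to 4 members of smallest p from each list with at least 3 measured members. Alternatives were DESeq2 1.42.0, RLE factors, scaling by total counts, no filter on low counts, a fit of the 2 compared diets alone, the replicate number as a block, leaving out each library, limma without trend, and a term for the library-number series in sperm. An alternative pseudocount had no use, since no table holds linear normalized values. Chosen after seeing the data were a fit without 3 eWAT libraries that held over 1000 CPM of miR-200b-3p, a fit of liver without miR-122-5p, and a fit of the sperm miRNAs above the lowest value in at least 6 libraries.

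Depth was 7017730 to 14394584 counts per library in liver and 7481038 to 13022536 in eWAT; the depth of the sperm libraries is unknown. A count of 0 allows a level of up to 3 counts, 0.208 to 0.427 CPM in liver and 0.230 to 0.401 CPM in eWAT, which covers counting error only, since reads without molecular identifiers are not independent molecules. This floor is taken over total counts, without the TMM factor, so it compares only roughly with TMM-scaled means. The fit was tested on simulated data with the library sizes and spreads of these tables and 200 changed miRNAs (20 in sperm). In liver it recovered 79.8% of miRNAs changed 2-fold and 49.5% of those changed 1.5-fold, in eWAT 58.6% and 16.5%, in sperm 50.0% of those changed 2-fold. The interaction test recovered 35.0% of 2-fold differences. Each rate comes from a single simulated data set. Far fewer miRNAs were called in liver (24 in HF against LF), and the adjustment is stricter where fewer miRNAs change. The rates may thus be too high for contrasts with few or no calls. Libraries of a group were checked for repeated content, and no pair came close to equal counts. Positions are those of GRCm38 hairpins in the reference annotation. Python 3.11.15 and matplotlib 3.10.9 drew the figures. Members of the let-7 family, and of miR-465, differ by few bases, so counts of single members are uncertain.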

Results

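Mature microRNAs (miRNAs) were measured by small RNA sequencing in liver, epididymal white adipose tissue (eWAT, the fat pad beside the testis) and sperm of C57BL/6 males. There were 18 libraries per tissue, 6 for each diet: low fat for 18 weeks (LF), high fat for 18 weeks (HF), or high fat for 9 weeks followed by low fat for 9 weeks (HFLF). Liver libraries held 7017730 to 14394584 counts over 593 to 706 detected miRNAs, and eWAT libraries 7481038 to 13022536 counts over 827 to 934 detected miRNAs. In liver the hepatocyte miRNA miR-122-5p took 44.7% ± 3.17 (SD, n = 18) of the counts, followed by let-7f-5p (9.30% ± 0.81), let-7a-5p (6.64% ± 0.48), miR-21a-5p (5.14% ± 0.75) and let-7c-5p (3.93% ± 0.45). In eWAT miR-143-3p took 11.98% ± 5.19 and let-7f-5p 11.9% ± 0.93, followed by miR-26a-5p (9.78% ± 1.00), let-7c-5p (8.65% ± 1.17) and let-7a-5p (8.53% ± 1.39). The sperm table gave 79 miRNAs chosen by the authors, on a log2 scale, in clusters of 35, 28 and 16. There miR-143-3p, let-7a-5p, miR-10b-5p, miR-10a-5p and miR-34c-5p had the highest values. The names in the files carry the prefix mmu-, left off below.

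The comparison of HF with LF asks what a lasting high-fat diet changed in fat tissue. In eWAT, 8 of 13 leukocyte miRNAs rose and 8 of 12 adipocyte miRNAs fell, while 1 adipocyte miRNA rose. Both lists moved by fry (adjusted p = 0.000295 and 0.000579; adjusted p = 0.158 and 0.157 with an estimated correlation). The leukocyte miRNAs miR-342-3p and miR-342-5p rose from 99.7 ± 10.5 to 870.2 ± 676 CPM (TMM-scaled abundance, mean ± SD, n = 6 each) and from 6.57 ± 1.18 to 52.4 ± 42.3 CPM. The neighbouring miR-221-3p and miR-222-3p, which repress the cell-cycle inhibitor p27, rose 4.63-fold and 5.36-fold. The adipocyte and smooth muscle miRNA miR-143-3p fell from 182300 ± 85820 to 70510 ± 21880 CPM, and miR-30a-5p fell from 39020 ± 7990 to 18440 ± 6498 CPM. All 3 members of the miR-29 family, which represses collagens, were lower in HF.

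Of 571 miRNAs tested in eWAT, 112 were higher and 87 lower in HF (edgeR, adjusted p below 0.05), and 77 separated the groups without overlap, where chance gives 0.216%. The largest rises were those of miR-504-5p (log2 fold change 3.21, SE 0.60, adjusted p = 0.000598), miR-673-3p (3.14, adjusted p = 0.000523; its LF mean of 0.243 CPM lies at the floor of 0.230 to 0.401 CPM, so the size is uncertain), miR-342-3p (3.13, SE 0.43, adjusted p = 0.000192) and miR-342-5p (7.97-fold, adjusted p = 0.000312). They were followed by miR-222-3p (2.42, SE 0.39), miR-335-3p (2.22), miR-221-3p (2.21, SE 0.35), miR-1983 (2.19), miR-665-3p (2.12) and miR-5107-5p (2.04), with adjusted p from 0.000312 to 0.0109. These 10 were higher in 6 of 6 HF libraries. miR-143-3p had a log2 fold change of -1.37 (SE 0.28, adjusted p = 0.00124) and miR-30a-5p of -1.08 (SE 0.20, adjusted p = 0.000524), each lower in 6 of 6 libraries. The hairpin of miR-342 lies on chromosome 12 at 108658620 to 108658718 in an intron of Evl, and that of miR-504 on chromosome X at 59097658 to 59097736 in an intron of Fgf13. The hairpins of miR-221 and miR-222 lie on X from 19146294 to 19146971 outside other genes of their strand. Scaling mattered for the balance of rises and falls: the median log2 fold change of all miRNAs was 0.03 with TMM and 0.31 with total counts. With total counts 205 miRNAs were higher and 53 lower, 165 of the 258 shared with the 199 calls above. With RLE factors the majority turned to falls (100 higher, 111 lower, 187 shared), as it did with DESeq2 (106 higher, 121 lower, 187 shared).

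**Figure D1:**
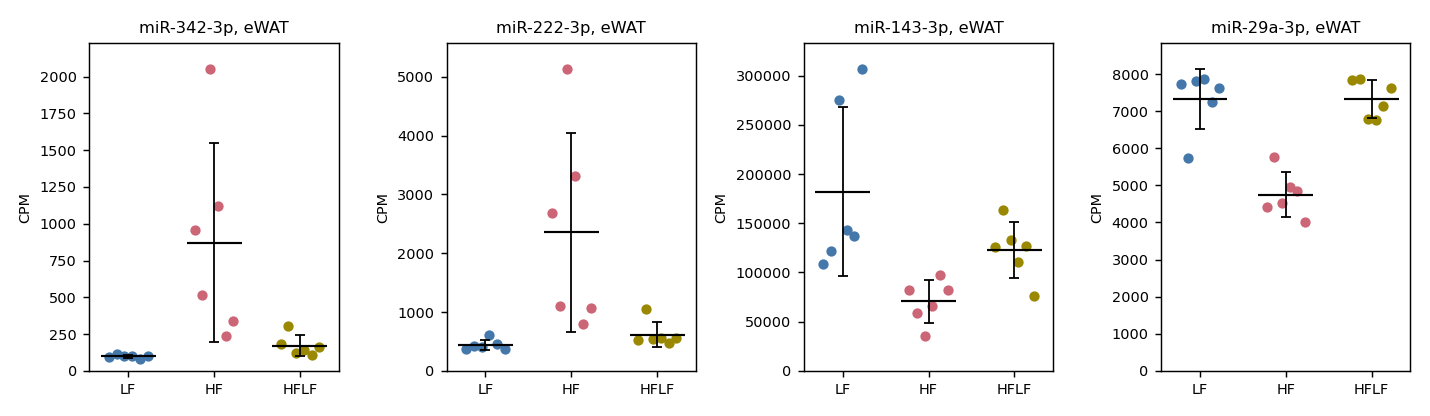
Abundance (CPM, TMM-scaled) of 4 miRNAs in eWAT by diet; each point is a library, the horizontal line the mean and the bar 1 SD (n = 6). miR-342-3p averaged 99.7 CPM in LF, 870.2 in HF and 170.5 in HFLF, while miR-29a-3p averaged 7334, 4753 and 7339 CPM.

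Markers of immune cells rose in eWAT under HF. Of 13 measured leukocyte and macrophage miRNAs, 8 were higher and none lower (8 adjusted over the list alone), and the list moved up (fry adjusted p = 0.000295; adjusted p = 0.158 with an estimated correlation). Beside miR-342, they included miR-155-5p (log2 fold change 0.94, SE 0.14, adjusted p = 0.000291), which promotes inflammatory activation, and the myeloid miR-223-3p (0.82, SE 0.13, adjusted p = 0.000312), both higher in 6 of 6 libraries. The imprinted Dlk1-Dio3 cluster, a large group of miRNAs expressed from the maternal chromosome, also rose: 24 of 42 measured members were higher and none lower (29 adjusted over the list alone; fry adjusted p = 0.00155; adjusted p = 0.197 with an estimated correlation). Among them were miR-409-3p (1.21), miR-543-3p (1.37), miR-431-5p (1.54) and miR-433-3p (1.36), with adjusted p from 0.000434 to 0.000524 and 6 of 6 libraries higher. In the lipid and fatty liver list of 17 measured miRNAs, 5 rose and 8 fell (14 adjusted over the list alone; fry adjusted p = 0.609). Those that rose included miR-132-3p (1.15, adjusted p = 0.000365), a target of the CREB transcription factor, and miR-34a-5p (0.96, adjusted p = 0.000386), a target of p53. That list moved up with total counts (adjusted p = 0.0032) and down with RLE factors (adjusted p = 0.00922), so its direction rests on the scaling. The fibroblast and stellate cell list had 3 of 12 members higher and 2 lower (5 adjusted over the list alone; fry adjusted p = 0.0580). Its call appeared without LF 4 (adjusted p = 0.0218), HF 2 (0.0317), HF 5 (0.0193) or HF 6 (0.0368), with total counts (0.0032), with the replicate block (0.0426) and without LF 4, LF 5 and HFLF 4 (0.0307). Of 11 measured members of miR-17-92 and its paralogs, 2 rose, miR-17-5p (0.51, adjusted p = 0.0101) and miR-20a-5p (0.49, adjusted p = 0.0172), each also called over the list alone (fry adjusted p = 0.0729, 0.0216 without HF 5 and 0.00267 with total counts). The call of miR-20a-5p ended without LF 6 (adjusted p = 0.0574), with DESeq2 (0.0752), RLE factors (0.0559), no filter on low counts (0.0688) or only both diets compared (0.0636), and without LF 4, LF 5 and HFLF 4 (0.0690). That of miR-17-5p ended with no filter (0.0567) or only both diets compared (0.0513). In the same list miR-93-5p was called lower with DESeq2 (0.0238) and RLE factors (0.0148), and miR-19a-3p higher with total counts (0.0223) and without HF 5 (0.0467).

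Markers of fat cells and of several other cell types fell in the same tissue. Of 12 adipocyte miRNAs, 8 were lower and 1 higher (11 adjusted over the list alone; fry adjusted p = 0.000579; adjusted p = 0.157 with an estimated correlation). Beside miR-143-3p and miR-30a-5p, miR-145a-5p fell (log2 fold change -0.92, adjusted p = 0.00511). All 3 miR-29 members fell (3 adjusted over the list alone; fry adjusted p = 0.0000738; adjusted p = 0.157 with an estimated correlation): miR-29a-3p by 0.63, miR-29b-3p by 0.90 and miR-29c-3p by 0.94 on the log2 scale (fold changes -0.63, -0.90 and -0.94; 6 of 6 libraries each). In the miR-30 family 3 of 5 members fell (5 adjusted over the list alone; fry adjusted p = 0.000103; adjusted p = 0.143 with an estimated correlation), among them miR-30e-5p (-0.77, adjusted p = 0.000529). Of 8 measured hepatocyte miRNAs 6 fell (7 adjusted over the list alone; fry adjusted p = 0.000212; adjusted p = 0.143 with an estimated correlation). These included miR-215-5p (-2.53, SE 0.54, adjusted p = 0.00153), miR-194-5p (-2.23, SE 0.52, adjusted p = 0.00332) and miR-101a-3p (-0.79, adjusted p = 0.000405), and other tissues express them too. Without the eWAT libraries LF 4, LF 5 and HFLF 4, treated below, the log2 fold change of miR-194-5p was -0.67 (adjusted p = 0.00299) and that of miR-215-5p -2.77 (adjusted p = 0.00209). The fall of the hepatocyte list member miR-192-5p, singled out after its values were seen, went from log2 fold change -2.47 (adjusted p = 0.00754) to -0.48 (adjusted p = 0.147), so much of the fall of miR-194-5p and miR-192-5p rested on those libraries. The list still passed without the 3 libraries. Among 4 striated muscle miRNAs 3 fell (3 adjusted over the list alone; fry adjusted p = 0.000974; adjusted p = 0.157 with an estimated correlation). miR-1a-3p fell by 1.85 (log2 fold change -1.85, adjusted p = 0.00322, 6 of 6 libraries). The calls of miR-133a-3p (-1.52) and miR-499-5p (-1.67) ended without LF 3 (adjusted p = 0.0721) and without LF 6 (adjusted p = 0.0601), respectively, and with only both diets compared (0.0513 and 0.0541), that of miR-133a-3p also with the replicate block (0.0566). In the brown and beige fat list 4 of 10 members fell and 1, miR-455-3p (1.04, adjusted p = 0.00421), rose (6 adjusted over the list alone; fry adjusted p = 0.00308; adjusted p = 0.197 with an estimated correlation and adjusted p = 0.398 with total counts). Of 5 erythroid miRNAs 2 fell, miR-144-5p and miR-144-3p (5 adjusted over the list alone; fry adjusted p = 0.0139; adjusted p = 0.299 with an estimated correlation and 0.0750 with total counts). The call of miR-144-3p (-0.97) ended without LF 4, LF 6, HF 2, HF 3 or HF 4 (adjusted p from 0.0660 to 0.116), with no filter on low counts (0.0626) and with only both diets compared (0.0852). With total counts (0.0522 and 0.0942) and without LF 4, LF 5 and HFLF 4 (0.0510 and 0.0713) neither miR-144-5p nor miR-144-3p was called. Of 9 miRNAs from studies of sperm after paternal stress or diet, 5 fell and miR-532-3p (0.65, adjusted p = 0.0036) rose (6 adjusted over the list alone; fry adjusted p = 0.000212; adjusted p = 0.143 with an estimated correlation). The endothelial list, with 2 measured members, and the X-linked testis cluster, with 16 (fry adjusted p = 0.352), had no call, also over the lists alone. Without HF 1, 3 members of the X-linked cluster were called lower: miR-465a-5p (log2 fold change -5.09, adjusted p = 0.00689), miR-878-5p (-3.19, adjusted p = 0.0349) and miR-881-3p (-3.48, adjusted p = 0.0422). With DESeq2 and RLE factors, calls appeared for miR-451a (adjusted p = 0.0274 and 0.0280) and miR-30d-5p (0.0144 and 0.00708), both lower.

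Among the deepest falls in eWAT were those of epithelial miRNAs, and most of these were highest in 3 libraries; miR-205-5p was an exception. Epithelial miR-200b-3p stood at 4398 CPM in LF 4, 2153 CPM in LF 5 and 1066 CPM in HFLF 4, against 486 CPM in LF 3, 262 CPM in LF 2 and 34.6 to 79.6 CPM in the other libraries. All 5 measured members of the epithelial list were lower in HF (5 adjusted over the list alone; fry adjusted p = 0.0379; adjusted p = 0.299 with an estimated correlation): miR-200a-3p (log2 fold change -4.89, SE 1.14), miR-429-3p (-4.79), miR-200b-3p (-4.65, SE 1.15), miR-200c-3p (-4.64) and miR-205-5p (-4.45, SE 1.10), with adjusted p from 0.00322 to 0.0145 and 6 of 6 HF libraries under the LF mean. That list's call ended without LF 3, LF 4, LF 5 or any HF library (adjusted p from 0.0524 to 0.0773). The other miRNAs of largest fall were miR-135a-5p (-7.42, SE 2.06, adjusted p = 0.00973), miR-375-3p (-4.63, adjusted p = 0.0393), miR-200a-5p (-3.81), miR-34b-5p (-3.80, adjusted p = 0.0371) and miR-200b-5p (-3.74). The calls of miR-375-3p and miR-34b-5p ended without LF 4, LF 5, HF 2, HF 3, HF 4, HF 5 or HF 6 (adjusted p from 0.0507 to 0.133), and that of miR-200b-5p without LF 4 (adjusted p = 0.0571). With the replicate block the calls of miR-135a-5p (log2 fold change -4.04, adjusted p = 0.0587), miR-200c-3p (-3.12, 0.0755), miR-205-5p (-2.81, 0.0555), miR-375-3p (0.124), miR-34b-5p (0.147) and miR-200b-5p (0.0796) ended. Those of miR-375-3p and miR-34b-5p also ended with no filter on low counts (0.0504 and 0.0511) or only both diets compared (0.0515 and 0.0600). Of 5 measured germ cell miRNAs of the miR-34b/c and miR-449 families, 3 were called lower (4 adjusted over the list alone; fry adjusted p = 0.163): miR-34b-5p, miR-34c-3p (-3.04) and miR-34c-5p (-2.87). The related miR-34b-3p was called lower with DESeq2 (adjusted p = 0.0159), with RLE factors (0.0414) and without LF 1, LF 3, LF 6 or HF 1 (0.0195 to 0.0361). The calls of miR-34b-5p, miR-34c-3p and miR-34c-5p ended without LF 4 (adjusted p = 0.133, 0.142 and 0.190), without LF 5 (0.0669, 0.0553 and 0.0806), without HF 2, HF 3, HF 4, HF 5 or HF 6 (0.0503 to 0.0995), with the replicate block (0.147, 0.112 and 0.188), and without LF 4, LF 5 and HFLF 4 (0.850, 0.729 and 0.908). Both members of the miR-183 cluster measured were lower, also over the list alone, among them miR-182-5p (-2.86, SE 0.64, adjusted p = 0.0024). Without LF 4, LF 5 and HFLF 4, an alternative chosen after seeing the data, all 5 members of the epithelial list stayed called: miR-200a-3p (log2 fold change -2.17, adjusted p = 0.00209), miR-200b-3p (-2.20, 0.00289), miR-200c-3p (-2.18, 0.0397) and miR-429-3p (-1.67, 0.0179) with smaller falls, and miR-205-5p (-4.93, 0.00362) without one. miR-135a-5p then had a log2 fold change of -2.28 (adjusted p = 0.0165), and the calls of miR-200a-5p (0.108) and miR-200b-5p (0.124) ended. In that fit miR-375-3p had a log2 fold change of -0.98 (adjusted p = 0.564) and miR-34b-5p of 0.31 (adjusted p = 0.85), and 171 miRNAs were called in eWAT, 158 of them among the 199.

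**Figure D2:**
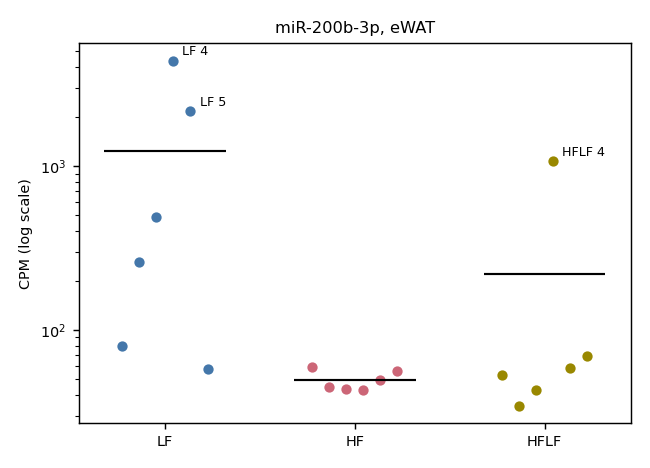
Abundance (CPM, TMM-scaled, log axis) of miR-200b-3p in the 18 eWAT libraries by diet; each point is a library and the line is the arithmetic mean of a diet. LF 4 (4398 CPM), LF 5 (2153 CPM) and HFLF 4 (1066 CPM) lie above 1000 CPM.

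The comparison of HFLF with HF asks what changed in fat when the high-fat diet ended. Most of the eWAT changes ran in the opposite direction to those of HF against LF. miR-342-3p and miR-342-5p fell by 2.35 and 2.32 on the log2 scale (log2 fold changes -2.35 and -2.32, adjusted p = 0.00202 and 0.00251), and miR-222-3p (-1.93, SE 0.38, adjusted p = 0.00243) and miR-221-3p (-1.72, adjusted p = 0.00251) fell too. The miR-29 family rose in all 3 members (3 adjusted over the list alone; fry adjusted p = 0.000115; adjusted p = 0.157 with an estimated correlation), with miR-29a-3p at 7339 ± 513 CPM in HFLF against 4753 ± 602 CPM in HF (log2 fold change 0.63, SE 0.09, adjusted p = 0.00149). miR-30a-5p rose by 1.01 (SE 0.20, adjusted p = 0.00225), within a family of which 4 of 5 members rose (4 adjusted over the list alone; fry adjusted p = 0.000132; adjusted p = 0.157 with an estimated correlation).

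In all, 55 miRNAs were higher and 93 lower in HFLF than in HF, 56 without overlap (chance 0.216%), out of 571. With RLE factors 68 were higher and 86 lower, with DESeq2 69 and 91. With total counts 25 were higher and 138 lower, 118 of them shared, and the median log2 fold change moved from -0.09 to -0.20. The largest fitted rise was that of miR-5615-5p (3.06, adjusted p = 0.0209), but its HF mean of 0.134 CPM lies under the eWAT floor of 0.230 to 0.401 CPM, so its size is no measured fold. Next were miR-3076-3p (1.91, adjusted p = 0.00225), miR-215-5p (1.57, adjusted p = 0.0356), miR-499-5p (1.51, adjusted p = 0.0433) and miR-203b-3p (1.47, adjusted p = 0.00251). Of these the call of miR-5615-5p ended without HF 3 (adjusted p = 0.0534). Those of miR-215-5p and miR-499-5p ended without HF 1, HF 3, HF 4, HFLF 1, HFLF 4 or HFLF 5, that of miR-215-5p also without HF 5, and that of miR-499-5p also without HFLF 2, HFLF 3 or HFLF 6 (adjusted p from 0.0501 to 0.109). With no filter on low counts all 3 ended (0.0507, 0.0641 and 0.0790), and with total counts miR-215-5p (0.0568) and miR-499-5p (0.0605) did, as they did without LF 4, LF 5 and HFLF 4 (0.0948 and 0.0526) and miR-215-5p with only both diets compared (0.0518). Beside miR-342 and miR-222-3p, miR-380-3p (-1.79, adjusted p = 0.0147) and miR-23b-5p (-1.77, adjusted p = 0.00251) fell most. The adipocyte list moved up with 7 of 12 members higher (9 adjusted over the list alone; fry adjusted p = 0.00172; adjusted p = 0.180 with an estimated correlation), and the hepatocyte list with 4 of 8 (4 adjusted over the list alone; fry adjusted p = 0.00455; adjusted p = 0.180 with an estimated correlation). The leukocyte list moved down with 6 of 13 lower (10 adjusted over the list alone; fry adjusted p = 0.00685; adjusted p = 0.273 with an estimated correlation), and the Dlk1-Dio3 cluster with 22 of 42 (30 adjusted over the list alone; fry adjusted p = 0.00448; adjusted p = 0.202 with an estimated correlation). The sperm-study list (3 of 9 higher, 4 over the list alone), the erythroid list (2 of 5, 3 alone) and the striated muscle list (1 of 4, 1 alone) moved up as well, with fry adjusted p = 0.00078, 0.00789 and 0.00818; adjusted p = 0.157, 0.219 and 0.202 with an estimated correlation. In the brown and beige fat list 2 members rose and 2 fell (5 over the list alone; fry adjusted p = 0.0105; adjusted p = 0.221 with an estimated correlation and 0.297 with total counts), a call that ended without HF 4 (0.0577), HFLF 4 (0.0519) or HFLF 6 (0.0514). The fibroblast list passed without HF 5 (adjusted p = 0.0381, against 0.113) or HFLF 2 (0.0462) and with total counts (0.0213), as the miR-17-92 list did with total counts (0.0213, against 0.225) and the lipid list with RLE factors (0.0108, against 0.245). The epithelial list did not pass (0 of 5 called, 0 over the list alone; fry adjusted p = 0.575). Both median and mean of the X-linked list were negative (-0.56 and -0.51) while fry gave the direction as up (adjusted p = 0.744). The count of calls dropped to 91 without HF 3 and to 98 without HFLF 5.

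Of the 112 miRNAs higher in HF than in LF, 78 were called lower in HFLF than in HF, where independent lists would share 18.2. Of the 87 lower in HF, 46 were called higher in HFLF, where independent lists would share 8.38. Both contrasts use the HF libraries, so an opposite sign arises in part by design: the log2 fold changes correlated across the 571 miRNAs (miRNAs are not independent replicates) with r = -0.81, against -0.50 in 50 simulated data sets without a diet effect. Those simulations shared a mean of 0.02 calls, against 124 here. Without a diet effect hardly any miRNA is called in either contrast, so that comparison decides nothing. With the HF libraries divided so that the contrasts shared none, r had a median of -0.52 over 20 splits. The simulated -0.50 is no reference for this r, since it came from shared HF libraries. At the median of the 20 splits 57 calls were shared (0 to 65). Against LF, the HFLF libraries had a median log2 fold change of 0.20 over the 112 miRNAs, whose median in HF was 1.08. Over the 87 it was -0.24, against -1.04 in HF. The miRNAs were picked by HF against LF, and both contrasts use the LF libraries, so the same sign arises in part by design. Over the 571 miRNAs r was 0.77, against 0.51 in the simulations. With the LF libraries divided, r had a median of 0.51 over 20 splits (0.02 to 0.66). These medians alone thus do not show an incomplete return to LF levels.

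**Figure D3:**
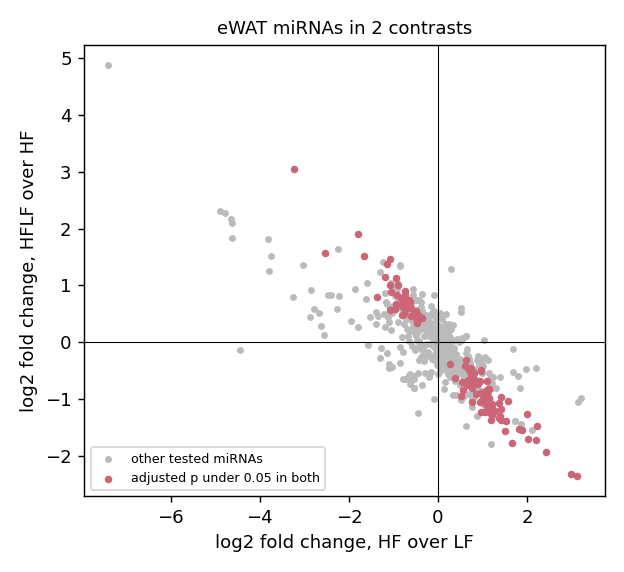
Log2 fold change of HF over LF (x axis) and of HFLF over HF (y axis) for the 571 miRNAs tested in eWAT; each point is a miRNA, in red where both adjusted p lie under 0.05. All 124 red points lie in the upper left (46) or lower right (78), the contrasts share the HF libraries, and r was -0.81.

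HFLF against LF asks how fat differed from that of mice always on low fat, after 9 weeks back on that diet. What was present at the switch of diet was not measured. No miRNA passed in eWAT (0 of 571 with edgeR, 65 at an unadjusted p below 0.05, 2 with DESeq2, and 6 without overlap where chance gives 0.216%). The smallest p belonged to the epithelial miR-205-5p (log2 fold change -4.60, SE 1.11), the neuron-expressed miR-326-3p (0.66, SE 0.16) and miR-504-5p (2.24, SE 0.57), each with adjusted p = 0.158 and 6 of 6 libraries beyond the LF mean of log2 CPM. miR-504-5p averaged 17.7 ± 18.7 CPM in LF, 164 ± 32.1 CPM in HF and 83.4 ± 39.9 CPM in HFLF. Its lowest HFLF library, HFLF 4 (log2 CPM 3.73), lay under that LF mean in CPM. DESeq2 called miR-205-5p (adjusted p = 0.00127) and miR-504-5p (adjusted p = 0.00961). There were 6 calls without LF 5, 12 without HFLF 4 and 7 without LF 4, LF 5 and HFLF 4, with miR-504-5p (adjusted p = 0.00731, 0.0236 and 0.00161) and miR-205-5p (0.0439, 0.0249 and 0.0274) among each. Without HFLF 4, 10 of the 12 were lower in HFLF, among them miR-200a-3p, miR-200b-3p, miR-429-3p, miR-182-5p and miR-183-5p (0.0236 each). Without the 3 libraries miR-200b-3p was called lower too (0.0352). No list passed; over the lists alone there were 3 calls in the epithelial list (fry adjusted p = 0.275), 4 in the lipid list (fry adjusted p = 0.829), 1 in the leukocyte list (fry adjusted p = 0.275) and 2 in the miR-183 cluster.

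In liver under the high-fat diet, 3 miRNAs with neighbouring hairpins fell, and miR-802-5p and miR-149-5p were among those that rose. let-7e-5p fell from 1456 ± 271 to 794 ± 165 CPM and miR-125a-5p from 4763 ± 936 to 2561 ± 394 CPM (mean ± SD, n = 6 each), and miR-99b-5p, made from the same stretch of DNA, fell from 815 ± 124 to 558 ± 71.7 CPM. miR-802-5p, known to rise in livers of obese mice, rose from 92.7 ± 26.8 to 184 ± 61.2 CPM. miR-149-5p rose from 47.4 ± 10.01 to 178 ± 85.8 CPM, miR-335-5p from 62.8 ± 12.4 to 107 ± 26.4 CPM, and miR-107-3p, which lowers insulin sensitivity, from 314 ± 29.8 to 478 ± 117 CPM. Several miRNAs of the X-linked testis cluster, at low levels in liver, were lower in HF.

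Of 422 miRNAs tested in liver, 11 were higher and 13 lower in HF than in LF, and 13 did not overlap (chance 0.216%). The log2 fold changes of the cluster were -0.90 for miR-125a-5p (SE 0.14, adjusted p = 0.000433), -0.87 for let-7e-5p (SE 0.14, adjusted p = 0.000534) and -0.55 for miR-99b-5p (SE 0.11, adjusted p = 0.00343), each lower in 6 of 6 libraries. With total counts that of miR-99b-5p was -0.34 (adjusted p = 0.0830). Their hairpins span 692 bp of chromosome 17, from 17830188 to 17830879, in Spaca6: those of miR-99b and let-7e in an intron, that of miR-125a in an exon. Further falls were those of miR-470-5p (-1.96), miR-465c-5p (-1.88, SE 0.30, adjusted p = 0.000534) and miR-592-5p (-1.86, SE 0.45, adjusted p = 0.0162). Also lower were the 3p arms of miR-465b (-1.36), miR-465a (-1.35) and miR-465c (-1.29), whose sequences are nearly identical. The macrophage miRNA miR-511-5p (2.01-fold, adjusted p = 0.00547), and miR-122-5p (-0.37, adjusted p = 0.0350) and miR-26a-5p (-0.34, adjusted p = 0.0107, and adjusted p = 0.15 with total counts) fell too. The last of the 13 was miR-23a-3p (-0.27, adjusted p = 0.0162), named after its values were seen; its call ended with total counts, with no filter on low counts (adjusted p = 0.0935) and without HF 4 (adjusted p = 0.0531). The rises were those of miR-3065-5p (3.90, SE 0.84, adjusted p = 0.00651, 3.26 CPM in HF and 0.220 CPM in LF, at the liver floor of 0.208 to 0.427 CPM, so the size is uncertain), miR-582-3p (3.04, adjusted p = 0.0248, 5 of 6 libraries), miR-149-5p (1.91, SE 0.29, adjusted p = 0.000433), and miR-802-5p (0.99, SE 0.20, adjusted p = 0.00492). Smaller rises were those of miR-32-5p (0.83), miR-335-5p (0.77, SE 0.15, adjusted p = 0.00333), miR-107-3p (0.60, adjusted p = 0.0186), miR-7a-5p (0.37, adjusted p = 0.0124, 5 of 6 libraries), miR-148b-3p (0.34, adjusted p = 0.0155), miR-340-5p (0.30) and the hepatocyte miR-194-5p (0.29). Direction held in 6 of 6 libraries for the others.

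Scaling and single libraries moved the liver calls. The median log2 fold change was -0.01 with TMM and 0.18 with total counts, under which 51 miRNAs were higher and 10 lower, 21 of them shared with the 24. DESeq2 called 45 (24 higher, 21 lower) and RLE factors 28 (15 higher, 13 lower). Calls appeared for miR-34a-5p with DESeq2 (adjusted p = 0.0438), with total counts (0.0147) and with no filter on low counts (0.00168), and for miR-33-5p with DESeq2 (0.0246), with total counts (0.0234), with only both diets compared (0.0386) and with the replicate block (0.0245), both higher. Without LF 4 there were 16 calls, and those of miR-582-3p, miR-32-5p, miR-340-5p, miR-470-5p, the 3p arms of miR-465, miR-122-5p and miR-194-5p ended (adjusted p from 0.0513 to 0.0872), while the count rose to 37 without LF 5, 36 without HF 6 and 49 without HF 5 (24, 23 and 24 of them among the 24). Calls also ended for miR-582-3p without HF 1 (adjusted p = 0.0807), miR-32-5p without LF 6 (0.0509) or HF 4 (0.0531), miR-470-5p without HF 3 (0.0541), and miR-340-5p and miR-194-5p without HF 2 (0.0643 each). That of miR-122-5p ended without LF 2, LF 3, HF 1, HF 2 or HF 4 (0.0580 to 0.0774), and those of the miR-465 3p arms without LF 2, HF 1, HF 2, HF 3 or HF 6 in part (0.0516 to 0.0731). With no filter on low counts miR-32-5p (0.0713) and miR-340-5p (0.0699) lost their calls, and with only both diets compared miR-32-5p (0.0566), miR-465a-3p (0.0515) and miR-122-5p (0.0566) did. Of 10 measured miRNAs of the X-linked testis cluster, 3 were lower (7 adjusted over the list alone; fry adjusted p = 0.00129; adjusted p = 0.0880 with an estimated correlation). The other lists did not pass in liver: over the lists alone 4 hepatocyte, 4 adipocyte and 5 lipid miRNAs were called (fry adjusted p = 0.492, 0.492 and 0.573), and all 3 miR-29 and 5 miR-30 members missed it (0.838 and 0.965). The adipocyte list passed without LF 6 (adjusted p = 0.0439) or HF 5 (adjusted p = 0.0371), the striated muscle list without LF 6 (0.05, against 0.0996), and the hepatocyte, adipocyte, brown fat and sperm-study lists with total counts (0.0231 each).

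**Figure D4:**
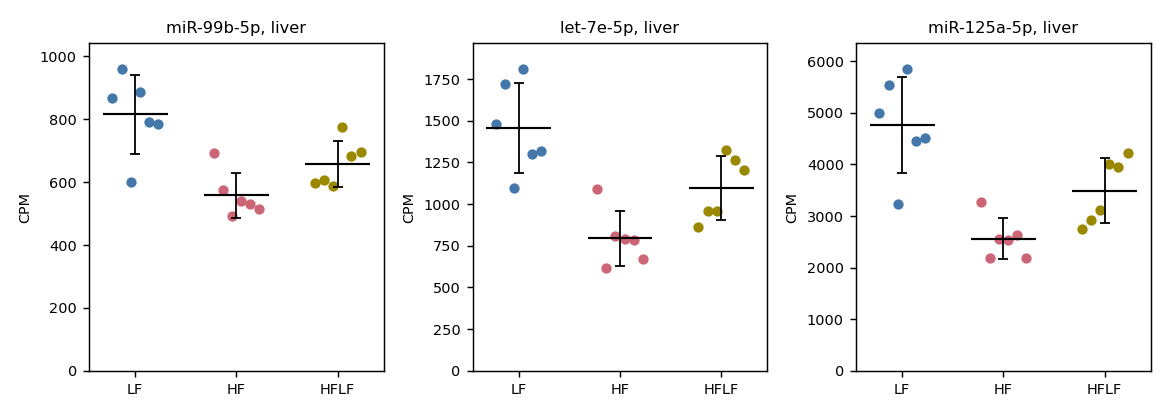
Abundance (CPM, TMM-scaled) of miR-99b-5p, let-7e-5p and miR-125a-5p in liver by diet; each point is a library, the line the mean and the bar 1 SD (n = 6). let-7e-5p averaged 1456 CPM in LF, 794 in HF and 1096 in HFLF.

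After the return to low fat no liver miRNA was called against HF or LF. The Dlk1-Dio3 cluster lay under both other diets (median log2 fold change -1.23 against LF and -0.73 against HF), without passing the list test (fry adjusted p = 0.170 and 0.684). let-7e-5p stood at 1096 ± 191 CPM in HFLF (log2 fold change 0.47 against HF, adjusted p = 0.118, and -0.41 against LF, adjusted p = 0.244). HFLF against LF had 0 of 422 calls with edgeR (51 at an unadjusted p below 0.05, 1 without overlap where chance gives 0.216%, 1 with DESeq2 and 15 without the filter on low counts). Its smallest p were those of miR-541-5p (-1.74, SE 0.39, adjusted p = 0.101) and miR-543-3p (-2.18, adjusted p = 0.198), both of the Dlk1-Dio3 cluster, and of the myeloid miR-223-3p (-0.73, adjusted p = 0.214, and the only call, 0.0294, without LF 5), each lower in 6 of 6 libraries. miR-541-5p was called with DESeq2 (0.0049), with no filter (0.000198) and with only both diets compared (0.0221), and the other 2 with no filter (0.0106 each). Of 12 Dlk1-Dio3 miRNAs 8 were called over the list alone (fry adjusted p = 0.170, 0.0366 without LF 6 and 0.0173 with only both diets compared). The hepatocyte, adipocyte, brown fat and miR-17-92 lists passed too without LF 6 (adjusted p from 0.0252 to 0.0466) and with only both diets compared (0.0163, 0.0163, 0.0173 and 0.0120). HFLF against HF had 0 calls with edgeR (65 at an unadjusted p below 0.05, 5 without overlap, 15 with DESeq2). Its smallest p were those of miR-465c-5p (1.42, SE 0.30, adjusted p = 0.0530), miR-425-5p (-0.29, adjusted p = 0.109) and miR-511-5p (0.78, adjusted p = 0.109), in 6 of 6 libraries each. With DESeq2 these 3 (0.0031, 0.0474 and 0.0474) and let-7e-5p (0.0474) were called. Calls appeared without HF 1 (3), HF 5 (2), HF 6 (6) or HFLF 5 (1). The X-linked list had a fry adjusted p of 0.0857 in HFLF against HF, and passed without HF 4, HF 5, HF 6, HFLF 3, HFLF 4 or HFLF 5 (adjusted p from 0.00658 to 0.0432), as the miR-17-92 list did without HF 6 (0.00540). Both passed without miR-122-5p (0.0272 each), an alternative chosen after seeing the data.

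In sperm, whose miRNAs may carry paternal effects to the embryo, the muscle miRNA miR-1a-3p separated HF from HFLF. Its values were 12.95 ± 0.26 in LF, 13.50 ± 0.31 in HF and 12.69 ± 0.17 in HFLF (log2 scale, mean ± SD, n = 6 each). It was the single call in sperm, lower in HFLF than in HF (log2 difference -0.81, SE 0.19, adjusted p = 0.0187, 6 of 6 libraries, without overlap). The authors chose the 79 miRNAs by a rule that the files do not give, so this adjusted p, like every p in sperm, may overstate the evidence. Whether the sperm samples held other cells was not tested, so the values cannot place the difference in sperm cells. The highest values there were those of the adipocyte and smooth muscle miRNA miR-143-3p. HFLF replicates 1 to 5 carry a series of library numbers that no other sperm library has, HFLF 6 included. With a term for that series the comparison rests on the 1 HFLF library of the first series: miR-1a-3p then had a difference of -0.99 (SE 0.29, adjusted p = 0.0711), and miR-106a-5p (1.01, adjusted p = 0.0193) and miR-3964 (1.60, adjusted p = 2.77e-09; above the lowest value in HFLF 6 only) were called instead. Each of the latter values assumes that 1 library varies like the other groups.

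HF against LF had 0 of 79 calls in sperm (limma; 24 at an unadjusted p below 0.05, 1 without overlap where chance gives 0.216%). The smallest p were those of miR-5099 (1.01, SE 0.30), miR-301a-3p (-0.80, SE 0.25) and miR-574-3p (1.25, SE 0.42), each with adjusted p = 0.0932 and 6 of 6 libraries. The 46 miRNAs above the lowest value in at least 6 libraries, a filter chosen after seeing the data, gave 13 calls, 9 higher and 4 lower, and the fit of both diets alone gave 5. There were 12 calls without HF 1, 4 without HF 3, 3 without HF 6 and 1 without LF 1 or LF 3. HFLF against LF had 0 calls (11 unadjusted, 0 without overlap). There miR-5121 (1.40), miR-380-3p (0.91, from the lowest value in all LF libraries) and miR-7218-5p (-1.22) had adjusted p = 0.315, in 6, 4 and 6 of 6 libraries. In HFLF against HF, 29 miRNAs had an unadjusted p below 0.05, and there were 10 calls without HF 1, 4 without HF 5, 2 without HFLF 3 and 4 without HFLF 4. The striated muscle list of 4 moved up in HF (2 over the list alone; fry adjusted p = 0.0445; adjusted p = 0.307 with an estimated correlation), a call that ended without LF 1, LF 2, LF 6, HF 2 or HF 4 (adjusted p from 0.0607 to 0.0968), with only both diets compared (0.0571) and with the replicate block (0.0658). It moved down in HFLF against HF (1 lower, 3 adjusted over the list alone; fry adjusted p = 0.00495; adjusted p = 0.242 with an estimated correlation and 0.165 with the series term). The 3 listed members of miR-17-92 moved up in HFLF against HF (0 called, 3 adjusted over the list alone; fry adjusted p = 0.00495; adjusted p = 0.153 with an estimated correlation). In HF against LF the lists of miR-17-92, lipid and leukocyte miRNAs missed the threshold (fry adjusted p = 0.0604, 0.0604 and 0.0668). The miR-17-92 list passed without LF 4 (0.0415), HF 1 (0.0499) or HF 5 (0.0493), and with the replicate block (0.0213). The lipid list passed without LF 4 (0.0415), LF 5 (0.0377) or HF 5 (0.0493), and the leukocyte list without HF 1 (0.0499), and both passed with the filter (0.0459 each). In HFLF against LF the miR-17-92 list passed with the series term (0.0285). Since the authors chose the 79 miRNAs, neither the single miRNAs nor the lists in sperm are independent evidence.

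The series title names let-7, a family that restrains cell growth and insulin signalling, so its summed level was compared in liver and eWAT, and let-7a-5p, the only member listed, in sperm. None of the differences between diets passed the test, in liver and eWAT with TMM scaling and in sperm on the deposited values. In liver log2 summed CPM was 17.90 ± 0.12 in LF, 17.87 ± 0.11 in HF and 17.87 ± 0.13 in HFLF (SD, n = 6 each; exact permutation p = 0.628 for HF against LF, adjusted p = 0.974 for all 3 contrasts). In eWAT it was 18.47 ± 0.18, 18.40 ± 0.13 and 18.43 ± 0.07 (exact permutation p = 0.476 for HF against LF, adjusted p = 0.658 for all 3 contrasts). With total counts the eWAT sum turned, to 0.24 higher in HF than in LF (exact permutation test, adjusted p = 0.0162) and 0.17 lower in HFLF than in HF (log2 difference -0.17, adjusted p = 0.00649). The liver sum turned too, to 0.16 higher in HF than in LF (exact permutation test, adjusted p = 0.0714), but did not pass. As a share of all counts let-7 took 33.2% ± 3.84 in LF, 39.0% ± 1.93 in HF and 34.6% ± 2.27 in HFLF of eWAT libraries. Sperm let-7a-5p was 16.25 ± 0.46 in LF, 16.64 ± 0.38 in HF and 16.14 ± 0.36 in HFLF (exact permutation p = 0.145, 0.654 and 0.0476 for HF against LF, HFLF against LF and HFLF against HF; adjusted p = 0.217, 0.654 and 0.143), and the last became 0.0390 without HFLF 3. With the term for the library-number series the sperm difference of HFLF to HF was -0.83 (SE 0.44, limma adjusted p = 0.325).

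Single members of let-7 moved in opposite directions in eWAT. let-7g-5p fell in HF (log2 fold change -0.43, SE 0.09, adjusted p = 0.00193, 6 of 6 libraries) and rose in HFLF against HF (0.41, adjusted p = 0.00501). let-7e-5p rose in HF (0.28, SE 0.10, adjusted p = 0.0401, 6 of 6 libraries) and fell in HFLF against HF (-0.39, adjusted p = 0.0102). let-7d-5p was called higher in HF without LF 1 (adjusted p = 0.0183), HF 1 (0.0178) or HF 5 (0.0312). The call of let-7e-5p in HF ended without LF 3 (adjusted p = 0.0915) or LF 6 (0.0641), with DESeq2 (0.286), RLE factors (0.147), no filter on low counts (0.108), only both diets compared (0.0603) or the replicate block (0.0511), and without LF 4, LF 5 and HFLF 4 (0.0758). That of let-7g-5p ended with total counts (-0.13, adjusted p = 0.139). The other 8 measured members were not called with TMM (1 call adjusted over the list alone; fry adjusted p = 0.520). With total counts 5 members rose, none fell, and the list moved up (adjusted p = 0.0032). With RLE factors let-7f-5p, the most abundant member, was called lower (-0.24, adjusted p = 0.0338). In liver let-7e-5p was the only one of 10 called (1 adjusted over the list alone; fry adjusted p = 0.573). The median of the family was 0.01, its mean -0.03. With total counts let-7f-5p (0.22, adjusted p = 0.0106) and let-7g-5p (0.20, adjusted p = 0.0147) were called higher in liver.

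**Figure D5:**
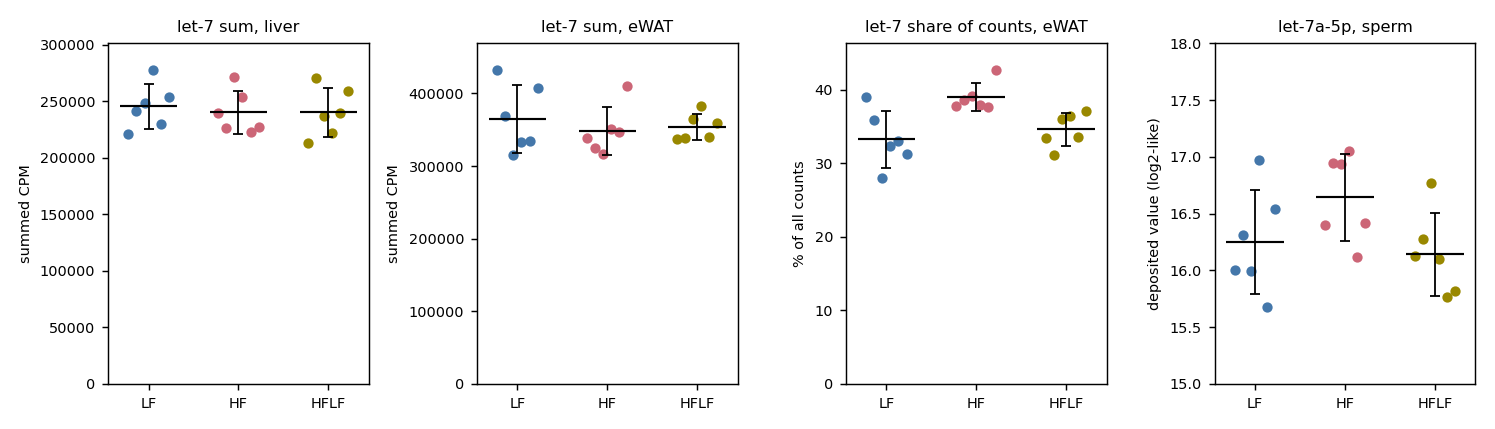
Summed let-7 in liver and eWAT (CPM, TMM-scaled), let-7 share of all counts in eWAT (%), and let-7a-5p in sperm (deposited log2-like value, axis from 15 to 18) by diet; each point is a library, the line the mean and the bar 1 SD (n = 6). The eWAT sums overlap between diets. With total counts, as the share shows, the HF mean (39.0%) lies above the LF mean (33.2%). The shares overlap as well, with LF 1 at 39.06% and HF 5 at 37.67%.

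Liver and fat differed in their response to the high-fat diet. The interaction of tissue and diet passed for 159 of 595 miRNAs in HF against LF (223 at an unadjusted p below 0.05), with a higher effect in eWAT for 70 and a lower effect for 89. With the replicate block it passed for 103 miRNAs, with total counts for 148, and for 130 without the eWAT libraries LF 4, LF 5 and HFLF 4. The joint fit kept miRNAs expressed in either tissue, while 422 passed the filter in liver and 571 in eWAT. Some of the 159 may thus be too low in liver to show a diet effect there, and how many was not counted. The liver cluster was among the 159: the effect in eWAT exceeded that in liver by 1.11 for mmu-let-7e-5p (SE 0.17, adjusted p = 8.53e-05), by 0.78 for mmu-miR-125a-5p (SE 0.17, adjusted p = 0.00172) and by 0.49 for mmu-miR-99b-5p (SE 0.14, adjusted p = 0.0113). In eWAT their log2 fold changes were 0.28, -0.06 and -0.01. The 3 miRNAs were singled out after their values were seen. For HFLF against LF the edgeR interaction passed for 0 miRNAs (69 at an unadjusted p below 0.05, smallest adjusted p = 0.0625), and for 3 without the eWAT libraries LF 4, LF 5 and HFLF 4.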

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

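The test of the let-7 share without miR-143-3p and the correlation within the liver cluster were set before their results were seen; the other tests of explanations in this part were chosen after the patterns were seen. In 30 of 388 groups of 6 libraries, 1 library lay far from the others, where chance gives about 1 in 20; the value given is its gap to the nearest library divided by the range of the group.

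In liver LF, the depth of LF 1 stood apart (14394584 counts, ratio 0.65), as did LF 1 for miR-107-3p (0.73), LF 3 for the epithelial (0.667), X-linked testis (0.669) and miR-29 lists (0.652) and for miR-3065-5p (0.729), and LF 4 for the 3p arms of miR-465b, miR-465a and miR-465c (0.658, 0.661 and 0.673). In liver HF it was HF 1 for the epithelial list (0.861) and miR-7a-5p (0.792). In liver HFLF it was HFLF 3 for the miR-30 list (0.669) and HFLF 4 for miR-21a-5p (0.633). In eWAT, miR-665-3p stood apart in LF 2 (0.648) and HF 3 (0.809), HF 1 for the epithelial list (0.656) and miR-200c-3p (0.717), HF 3 for miR-380-3p (0.877), and HFLF 2 for miR-222-3p (0.774) and miR-5615-5p (0.655). HFLF 4 of eWAT stood apart for the epithelial list (0.852), the sperm-study list (0.678), miR-504-5p (0.711, the lowest), miR-135a-5p (0.779), miR-200a-3p (0.868), miR-429-3p (0.873), miR-200b-3p (0.797), miR-200c-3p (0.775), miR-200a-5p (0.64) and miR-200b-5p (0.656).

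Of the miRNAs called in eWAT, 22 fell by more than 2 log2 units under HF, 5 of them in the epithelial and 3 in the germ cell list. For 15 of them LF 4 and LF 5 were the highest LF libraries and HFLF 4 the highest HFLF library, so tissue carried along at dissection is a candidate explanation for part of the fall; the libraries were picked by miR-200b-3p, itself a member, and miRNAs of 1 tissue move together. A lower level in every HF than in any LF library held for 3 of the 22. That test cannot decide against a general loss under HF, since in this contrast 199 miRNAs were called and only 77 separated without overlap. Without the 3 libraries 12 of all 22 were still called lower and the median log2 fold change of the 22 went from -3.24 to -1.75, which argues against these libraries as the whole cause. Lesser carry-over in other LF libraries and an effect of diet on epithelial cells stay open, and no list of epididymal miRNAs was tested.

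The share of let-7 in all eWAT counts was higher in HF (39.0% ± 1.93) than in LF (33.2% ± 3.84; SD, n = 6 each; log2 difference 0.24, exact permutation p = 0.0108). miR-143-3p took 16.2% ± 6.22 of counts in LF and 7.82% ± 2.15 in HF. With miR-143-3p left out of the total, the log2 difference of the let-7 share was 0.0955 (exact permutation p = 0.0758), so a share freed by the fall of miR-143-3p may account for most of the rise. More let-7 in fat under HF stays open: with TMM 1 measured member was called higher and 1 lower, with total counts 5 higher and 0 lower, with RLE factors let-7f-5p was called lower (log2 fold change -0.24), and the share of a total cannot be turned into an amount.

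The fall of let-7e-5p, miR-125a-5p and miR-99b-5p in liver under HF was weighed as the third pattern. Reads of other let-7 miRNAs counted as let-7e-5p at a constant share are argued against: of the 7 other let-7 members at least as abundant, the lowest log2 fold change was -0.11 (let-7a-5p, SE 0.08), against -0.87 (SE 0.14) for let-7e-5p. The share taken by miR-122-5p is argued against: miR-122-5p itself was lower in HF (log2 fold change -0.37), which would raise the others. Without it all 3 were still called lower (miR-99b-5p -0.54, SE 0.11, adjusted p = 0.00373) while the calls in liver went from 24 to 33. That fit adds little, since TMM scaling already limits the weight of a single abundant miRNA. The choice of scaling is argued against for let-7e-5p and miR-125a-5p, 2 of 2 called with TMM, RLE factors and total counts. It stays open for miR-99b-5p, called in 2 of the 3: its log2 fold change was -0.55 (SE 0.11) with TMM and -0.34 (SE 0.13, adjusted p = 0.0830) with total counts, so a smaller fall and a larger SE ended the call. Over 18 liver libraries, as deviations from diet means, let-7e-5p and the mean of its neighbours had r = 0.925 (rho 0.932, permutation p = 0.00001 each, the smallest that 100000 resamples can give, 1 relation tested). Without the 2 farthest libraries r was 0.917. Of 419 other miRNAs 0 correlated more with let-7e-5p. These were taken singly, while a mean of 2 miRNAs can carry less noise, so that ranking compares unlike measures. A shared primary transcript with a diet-dependent level is a hypothesis these values fit; transcription and processing were not measured.

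Liver and eWAT differed in their response to HF for 159 miRNAs by the interaction test (103 with the replicate block), and in 1 of 100 splits of the diet labels, the real one, were there as many (highest other 63). Some of the 159 may be too low in liver to show a diet effect there. The effect in eWAT exceeded that in liver by 0.4941 for miR-99b-5p, 1.11 for let-7e-5p and 0.7751 for miR-125a-5p. For HFLF against LF the real count was 0 (edgeR; 69 at an unadjusted p below 0.05; highest other 23); any split gives at least 0, so 100 of 100 says nothing about chance.

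Among 100 splits of the libraries, 1 (the real one) gave as many calls for HF against LF in liver (24, highest other 13) and eWAT (199, highest other 85), and for HFLF against HF in eWAT (148, highest other 50), and chance was excluded at that level. For the single call of sperm HFLF against HF, 9 of 100 splits gave as many (highest other 8), and chance was not excluded, among miRNAs that the authors had chosen. The comparisons with 0 calls, HFLF against LF in liver, eWAT and sperm, HFLF against HF in liver and HF against LF in sperm, had 100 of 100 (highest others 1, 24, 1, 3 and 2), which holds for any count of 0 and says nothing about chance. The split with 24 calls in eWAT may reflect a structure of these libraries other than diet or may be chance, which was not tested. For lists, 1 of 100 splits gave as many as the 11 in eWAT HF against LF (highest other 10), 2 as many as the 10 in HFLF against HF (highest other 10), and 1 as many as the 2 in sperm HFLF against HF (highest other 1). The splits cannot decide for the sperm lists, since the authors chose the miRNAs and HFLF replicates 1 to 5 have their own library-number series. Chance was not excluded for the 1 list in liver HF against LF (5 of 100 splits, highest other 1) and the 1 list in sperm HF against LF (6 of 100, highest other 1).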

How the results depend on the processing

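Leaving out miR-122-5p, leaving out eWAT LF 4, LF 5 and HFLF 4, and the sperm filter on low values were chosen after seeing the data; the other alternatives were set before. The cause was not tested for any change below unless the setting shows it (fewer libraries or miRNAs).

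Counts of called miRNAs moved by more than 1.5 times as follows. With DESeq2 there were 45 in liver HF against LF (24 with edgeR), 1 in HFLF against LF, 15 in HFLF against HF, and 2 in eWAT HFLF against LF. Total counts gave 61 in liver HF against LF, and RLE factors 1 in HFLF against HF. Without the filter on low counts there were 15 in liver HFLF against LF, 9 in HFLF against HF, and 89 (148 with it) in eWAT HFLF against HF. With only the diets compared there were 2 in liver HFLF against LF and 5 in sperm HF against LF. Without miR-122-5p 1 was called in liver HFLF against HF. Without LF 4, LF 5 and HFLF 4, 7 were called in eWAT HFLF against LF and 3 in the liver and eWAT difference for HFLF against LF. In sperm the filter gave 13 in HF against LF and 6 in HFLF against HF, and the library-number series term 2 each in HFLF against LF and HFLF against HF, resting on 1 HFLF library.

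With a replicate block there were 27, 0 and 0 calls in liver, 171, 0 and 130 in eWAT and 0, 0 and 2 in sperm (HF against LF, HFLF against LF, HFLF against HF), and 103 instead of 159 in the liver and eWAT difference for HF against LF. Whether equal numbers denote related animals is not stated: correlations between equal numbers in eWAT ran from -0.776 to 0.121 for LF and HF, -0.311 to 0.706 for LF and HFLF (numbers 1 and 4, at 0.701 and 0.706, matched their own number best) and -0.696 to 0.251 for HF and HFLF. LF 4 and HFLF 4 both held over 1000 CPM of miR-200b-3p. In the liver and eWAT difference the block instead joined the liver and eWAT libraries of a diet and number. Their correlations ran from -0.0859 to 0.112, and none matched its own number best.

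Directions reversed with total counts for the eWAT let-7 sum (0.236 in HF against LF, -0.174 in HFLF against HF), let-7i-5p (0.2925) and miR-98-5p (0.2259) in HF against LF, and in adjusted p for the let-7 (0.0032) and lipid (0.0032) lists in HF against LF and the let-7 list in HFLF against HF (0.0238). The liver let-7 sum changed sign in HF against LF, from -0.03 to 0.16, without passing (exact permutation test, adjusted p = 0.0714). Total counts moved the median of all eWAT miRNAs from 0.03 to 0.31 in HF against LF and from -0.09 to -0.20 in HFLF against HF. Without LF 4, LF 5 and HFLF 4, miR-34b-5p (0.3091) and miR-34c-5p (0.1376) reversed in HF against LF.

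Leaving out 1 library at a time gave 16 to 49 calls in liver HF against LF, 0 to 1 in HFLF against LF and 0 to 6 in HFLF against HF; 175 to 214, 0 to 12 and 91 to 160 in eWAT; and 0 to 12, 0 to 0 and 1 to 10 in sperm. The sperm let-7a-5p difference of HFLF to HF ran from -0.629 to -0.421, and passed without HFLF 3 (adjusted p = 0.0390). Of the other values, single miRNAs under other settings kept their call or lack of one in 3099 cases, lost their call in 89, gained one in 83 and reversed in 4. Lists did so in 720, 31, 23 and 3. A reversal needs a change of sign and a call in either fit. Values called in neither fit count as kept whatever their sign, so these numbers do not measure how often directions held. Without 1 library the numbers were 5667, 132, 81 and none for miRNAs and 1322, 17, 29 and none for lists. The pseudocount on the log scale did not apply to counts fitted by edgeR or to the deposited sperm values. Depth sets a floor of 0.208 to 0.427 CPM in liver (by total counts), near which miR-3065-5p stood in LF (0.220 CPM).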
